A study of Oreochromis niloticus with 6 samples.

How the data were processed

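Liver RNA of male Nile tilapia was sequenced as 6 libraries, 3 from fish in which elovl6 had been knocked down with antisense RNA and 3 from fish given a negative control. All fish ate a pellet diet with 5% palm oil. Per the labels' protocols, livers of 18 fish, 9 per group, were extracted, and equal amounts of RNA from 3 replicate tanks per group were pooled. The wording leaves open whether each library of a group held its own pool of fish or the same pool, so every p-value measures the spread between libraries of a group, which may be technical. Libraries were made from poly(A) RNA selected on oligo-dT beads and read as pairs of 150 bp. Per the submitters' processing notes, cutadapt 1.9 and HISAT were used. The HISAT version, the counting program, its treatment of strand and of reads with several matches, and the genome build are not given in the sources used here.

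A single table of the whole series was used. Per the file headers, it holds for each of 29528 genes the deposited read count and the deposited FPKM (fragments per kilobase of gene, scaled to the library total) of each library, with gene length, coordinates, product descriptions and pathway annotations. The counts were whole numbers that summed to different totals. The authors' FPKM equalled count divided by gene length and by the total count of the library in 100% of the values of each library, within a relative tolerance of 1e-05, so no other scaling between libraries had been applied by the authors before deposit. Columns were assigned to libraries by the sample names in the headers. No per-sample column of another study was present. Gene identifiers were matched to an NCBI table of the O_niloticus_UMD_NMBU assembly, which held 29526 of them. Start and end were equal in 99.99% of the matched genes, and linkage group names come from that table. It gave symbols to 6153 of the 19371 genes that the file names only by a locus number. The file and that table give different symbols for some genes, and the symbol of the file was kept.

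The test fixed before the data were examined was limma on log2(FPKM + 1), with edgeR in its place if the file held counts. It did, and edgeR's quasi-likelihood test on the deposited counts (edgeR 4.0.16, R 4.3.3, TMM scaling, no covariate, both groups) gave the main results. All comparisons are knockdown over control. Genes with a mean FPKM of at least 1 over the 6 libraries were tested, 11431 in number, which held 99.0% of all reads, and 18097 genes were left out. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 with no minimum fold. The standard error (SE) of a log2 fold change is its size divided by the square root of the quasi-likelihood F. All adjusted p-values for genes are from edgeR unless limma 3.58.1 or DESeq2 1.42.0 is named. Where a group had 0 reads, the fold is a lower bound against 3 reads over the 3 libraries of the group. Where it had 1 to 10 reads, the ratio of reads per library total is given with its exact binomial (Clopper-Pearson) 95% interval. Bounds and intervals cover counting error only. The level of elovl6 was also compared with a 2-sided exact permutation test, which cannot go below p = 0.1 for 3 against 3 libraries.

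Before the data were examined, 52 gene lists were fixed with 1570 symbols and 258 product names, covering lipid and glucose pathways, other liver functions, stress and immune responses, markers of other cell types and signs of RNA quality. The 45 lists with at least 5 tested members were compared with all other genes by camera on the edgeR fit, with a preset correlation between genes of 0.01, 2-sided, adjusted over the 45 lists. The test was repeated with an estimated correlation and with fry, which asks whether the genes of a list move, on balance, 1 way without comparing them with other genes. With an estimated correlation, camera also rests on the few residual degrees of freedom of the 6 libraries. Its p can then rise without a higher correlation. Counts of members adjusted over the list alone were equal to those over all genes in 39 lists. The exceptions were 1 member each in 6 lists. Too few members were tested in the lists estrogen response and egg yolk (4), endocrine pancreas (1), B and plasma cells (3), intestine (2), skeletal muscle (3), gonad and germ cells (0) and mitochondrial transcripts (0). The rule for named genes, fixed at the same time, took every tested elovl gene, the 10 genes per direction with the largest change whose groups did not overlap, and up to 4 changed members with the largest change of each lipid or glucose list and of each other list past the threshold. It gave 154 genes, all past the threshold and with no overlap between the groups. Some genes that the rule took are not reported here. Other genes named below were chosen after their values were seen and are marked so, apart from the elovl6-like copies below the filter, which are given for their names. Pathway annotations of the file were tested by camera only after the data had been seen.

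Libraries of a group differed by more than sampling noise, with a mean chi-square per gene of 3.14 to 4.50 over genes with at least 20 reads in a pair of libraries, so none was treated as a copy of another. Between groups this value was 354 to 381. The tests were tried on simulated counts of 11431 genes for this comparison of 3 against 3 libraries, with 200 genes changed. The edgeR test recovered 60% of the genes changed 1.5-fold, 88% of those changed 2-fold and 100% of those changed 4-fold, with 12 false calls. Camera called 0 of 50 simulated lists without change. Genes were simulated independently of each other, and far fewer changed than in the data. This trial therefore could not show false calls that come from correlation between genes. Alternatives were other filters, scalings, pseudocounts and tests, a replicate block, and leaving out each library in turn. Added after the data had been seen were DESeq2, limma on log2(FPKM + 1) in its new place as an alternative, scaling by library size alone, and leaving out the exocrine pancreas list before scaling.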

Results

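Gene expression was profiled in livers of male Nile tilapia (Oreochromis niloticus, a farmed freshwater fish) to ask what elovl6 regulates, with lipid and glucose metabolism named as the field of interest. The gene elovl6 encodes an elongase that lengthens palmitic acid, the main saturated fatty acid of palm oil. There were 3 libraries of elovl6 knockdown livers and 3 of negative control livers. Total counts were 14373269, 14341242 and 14973737 reads in knockdown libraries 1, 2 and 3, and 16547278, 15322360 and 17245179 in control libraries 1, 2 and 3. The correlation of log2(FPKM + 1) across genes was 0.991 to 0.995 within groups and 0.786 to 0.794 between them. The first principal component, which held 95.5% of the variance, separated the groups.

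The targeted gene, elovl6, was lower in every knockdown library. Its level was 37.6 ± 1.48 FPKM in the knockdown and 162 ± 1.53 FPKM in the control livers (SD, n = 3 each), 4.34-fold lower (log2 fold change -2.12, SE 0.05, adjusted p = 1.58e-22 by edgeR), with 3703 reads against 17960. The exact permutation test gave p = 0.1 (2-sided), the smallest that 3 against 3 libraries allow. The gene lies on linkage group LG2 from 13399803 to 13419682, on the minus strand. Reads over the whole gene were counted, and with the strand setting of the counting not given, reads of an antisense transcript could not be told from those of the gene. Among the other elongases, elovl5, which lengthens polyunsaturated fatty acids, fell further, from 173 ± 7.92 to 19.8 ± 1.24 FPKM (8.81-fold lower, log2 fold change -3.14, SE 0.05). The gene elovl8b was also lower (log2 fold change -1.01, SE 0.26, adjusted p = 0.00103). Its relative elovl8a, which like elovl8b the file describes as protein 4 of the elongase family, went the other way, from 2.88 ± 0.526 to 11.7 ± 0.871 FPKM, and elovl1b (log2 fold change 1.61, SE 0.11) was higher too. The elovl6-like copies elovl6l and LOC100697613 were below the filter, with 1 and 56 reads in the knockdown and 4 and 67 in the control libraries.

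**Figure D1:**
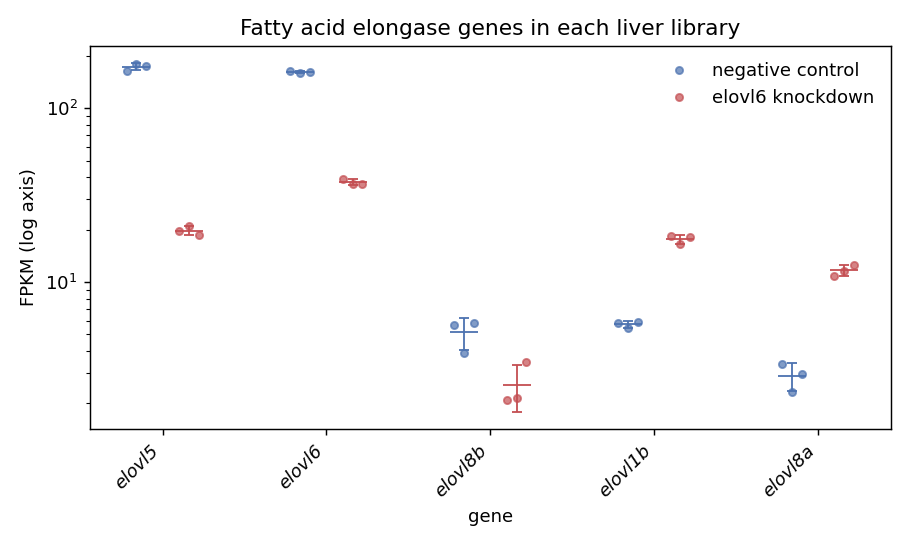
FPKM (log axis) of the 5 tested elongase genes in each library, as points, with the mean and SD of the 3 libraries per group as lines. Levels of elovl5 and elovl6 are lower and those of elovl1b and elovl8a higher in the knockdown libraries, and no knockdown point of any gene reaches the range of its controls.

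The knockdown livers differed from the controls in most of the expressed genes. Of 11431 genes tested, 4471 were higher and 4467 lower in the knockdown (78.2% changed, edgeR adjusted p under 0.05), of which 2523 and 2384 changed at least 2-fold and 407 and 275 at least 8-fold. The groups did not overlap in 9104 genes (79.6%), where chance gives 10%. Spread within groups was small, with a common biological coefficient of variation of 9.40%. Several of the largest changes were between reads in all libraries of a group and 0 reads in the other. In the knockdown, LOC102079354, a copy of vitelline membrane outer layer protein 1, was read 35674 times and in the controls 0 times (at least 13368-fold higher). A second copy, LOC109196230, reached 2367 ± 346 FPKM against 0.663 ± 0.893 FPKM (log2 fold change 11.85, SE 0.18). Its control libraries 1, 2 and 3 held 4, 20 and 0 reads, and with a library left out the log2 fold change ranged from 11.23 to 13.82. Read only in the knockdown libraries were also the serine protease gene tmprss5 (at least 425-fold higher), a beta-2 adrenergic receptor (LOC106098272, at least 532-fold higher), the dopamine receptor gene drd3 (at least 288-fold higher), ntn5, described in the file as netrin-1 (at least 302-fold higher) and an MHC class I-related gene (LOC100692201, at least 224-fold higher). The decoy receptor gene for interleukin-1, interleukin-1 receptor type 2 (LOC100702124), had 10776 reads against 3 (ratio 4038, 95% interval 1381 to 19584). Read only in the controls were LOC109201331, annotated as similar to programmed cell death 1 ligand 1, an inhibitor of T cells (at least 277-fold lower), an immunoglobulin heavy chain-like gene (LOC100700235, at least 138-fold lower), fam57a (at least 112-fold lower), unc45b, a chaperone of muscle myosin (at least 107-fold lower), and abcb10, a mitochondrial transporter (at least 88.7-fold lower). Another ligand 1 copy, LOC109199141, had 3 reads against 2846 (ratio 844, 95% interval 288 to 4094, lower). Several of these genes have same-named copies nearby, among which the counting could have split reads, so their individual values are uncertain. The summed reads of the 42 nearby copies of LOC100692201 differed by a log2 ratio of 0.074 between the groups. Those of the nearby copies of LOC102079354 (12.34), LOC100702124 (8.02), LOC109199141 (-9.10) and LOC109201331 (-6.08) stayed far apart.

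**Figure D2:**
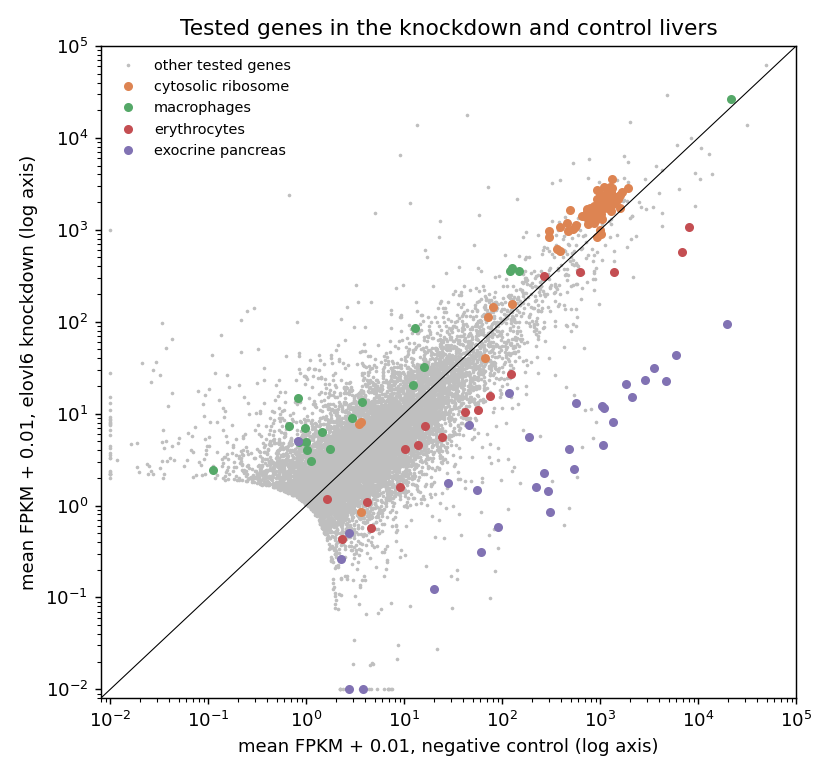
Mean FPKM of each tested gene in the knockdown against the control libraries (both + 0.01, log axes, n = 3 per group), with the line of equality and 4 gene lists in colour. Of the 31 exocrine pancreas genes 30 lie below the line, and of the 83 ribosomal genes 78 were higher. Points at the left and lower edge have 0 reads in a group.

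Genes of fatty acid synthesis changed in both directions, and no fixed list of lipid metabolism passed the threshold as a whole. Of 25 genes of fatty acid synthesis and elongation 11 rose and 12 fell (median log2 fold change -0.10, camera adjusted p = 0.447). The 2 copies of stearoyl-CoA desaturase, which makes monounsaturated fatty acids, moved apart. The scd copy rose from 57.8 ± 0.837 to 1434 ± 16.1 FPKM (24.7-fold higher, log2 fold change 4.63, SE 0.03), and scdb fell from 62.6 ± 0.3 to 1.79 ± 0.384 FPKM (35.2-fold lower, log2 fold change -5.14, SE 0.09). The gene me1, an NADPH source of lipid synthesis, was higher (log2 fold change 4.03, SE 0.23). In polyunsaturated fatty acid synthesis 4 of 7 genes rose and 3 fell (adjusted p = 0.66), the largest rise being in a fatty acid desaturase 2 copy, LOC100700077 (log2 fold change 4.84, SE 0.13). Of 26 cholesterol genes 8 rose and 14 fell (median -0.33, adjusted p = 0.501). Transcripts of the rate-limiting reductase hmgcra fell 2.77-fold (log2 fold change -1.47, SE 0.03) and of sc5d by 2.87 on the log2 scale, whereas insig1, which restrains the pathway, rose (log2 fold change 2.52, SE 0.05) and so did ldlr (1.49, SE 0.05). For triglyceride synthesis and lipid droplets 7 of 18 genes rose and 8 fell (adjusted p = 0.224), with lower fitm2, mogat3a and cidec (log2 fold changes -2.47, -2.20 and -1.68) and higher dgat1a (1.55).

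Lipases that release stored fat were among the genes that rose. In the list of lipolysis and lipophagy 11 of 13 genes rose and 1 fell (median log2 fold change 1.06, camera adjusted p = 0.128). Adipose triglyceride lipase, pnpla2, rose from 0.845 ± 0.087 to 13.4 ± 1.1 FPKM (log2 fold change 3.98, SE 0.14) and hormone-sensitive lipase, lipea, from 1.85 ± 0.238 to 26.3 ± 0.623 FPKM (3.82, SE 0.10). The member that fell, cel.2 (log2 fold change -6.89, SE 0.09), encodes a lipase secreted by the pancreas and belongs to the exocrine pancreas list too. Leaving out that list before scaling also took cel.2 out of the lipolysis list, which then passed the threshold (camera adjusted p = 0.00135). With cel.2 kept, the lipolysis list passed with limma on log2(FPKM + 1) (adjusted p = 0.00953). Its adjusted p ranged from 0.00135 to 0.362 over the camera alternatives. Of 31 genes of mitochondrial fatty acid oxidation 10 rose and 20 fell (median -0.51, adjusted p = 0.19), among them cpt2, which reforms acyl-CoA inside mitochondria (log2 fold change -2.79, SE 0.15), the fatty acid sensor pparab (-2.39, SE 0.06) and hadhab (-1.58, SE 0.06), while crat was higher (2.07, SE 0.12). Without a filter on low values the list passed as lower (adjusted p = 0.0412, range over the camera alternatives 0.0412 to 0.407). In the peroxisomal list 7 of 21 genes rose and 12 fell (adjusted p = 0.22), with lower slc27a2, acox3 and cyp4v2a (log2 fold changes -1.99 to -1.20). It too passed as lower without a filter (adjusted p = 0.032, range over the camera alternatives 0.032 to 0.494). Of 16 genes of fatty acid uptake and binding 6 rose and 9 fell (adjusted p = 0.66). The liver fatty acid-binding protein fabp1 rose 10.1-fold, from 525 ± 11.5 to 5346 ± 86.1 FPKM. In the lipoprotein list 10 of 25 genes rose and 14 fell (adjusted p = 0.917). Apolipoprotein Eb, apoeb, rose from 766 ± 11.7 to 5899 ± 54.9 FPKM (log2 fold change 2.94, SE 0.03). An apolipoprotein D copy (LOC100698328) had 1856 reads against 9 (ratio 232, 95% interval 122 to 508), and an angiopoietin-related protein 3 copy (LOC100689785), an inhibitor of lipoprotein lipase, had 3 against 318 (ratio 94.3, 95% interval 32 to 460, lower). Of the file's lipid pathway annotations, tested after the data had been seen, some did pass. Fatty acid degradation was lower (13 of 46 genes rose and 29 fell, median -0.71, camera adjusted p = 0.00095, adjusted p = 0.231 with an estimated correlation), and so was steroid biosynthesis (6 of 23 rose and 12 fell, median -0.38, adjusted p = 0.015, adjusted p = 0.244 with an estimated correlation). Glycerolipid metabolism was called lower with 20 of 52 genes higher and 20 lower (median -0.02, adjusted p = 0.0304, adjusted p = 0.244 with an estimated correlation). Genes of the exocrine pancreas list were left in these annotations, and their part in the lower calls was not tested. Regulation of lipolysis in adipocytes was higher (28 of 42 rose and 11 fell, median 0.75, adjusted p = 0.0357, adjusted p = 0.231 with an estimated correlation). Fatty acid biosynthesis (8 of 17 higher, 6 lower, adjusted p = 0.947) and fatty acid elongation (14 of 28 higher, 11 lower, 0.981) did not pass, nor did cholesterol metabolism (22 of 52 higher, 22 lower, adjusted p = 0.35) and peroxisome (27 of 83 higher, 46 lower, 0.0961).

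Key enzymes of glucose metabolism changed by up to 87.6-fold, in both directions within a pathway. Glucokinase, gck, which phosphorylates glucose in hepatocytes, fell from 803 ± 29.6 to 11.3 ± 2.26 FPKM (71.8-fold lower, log2 fold change -6.17, SE 0.08). Cytosolic phosphoenolpyruvate carboxykinase, pck1, which commits carbon to glucose production, fell from 151 ± 4.69 to 1.73 ± 0.203 FPKM (87.6-fold lower, log2 fold change -6.45, SE 0.07). In contrast, glucose-6-phosphatase, g6pc, which releases free glucose, rose from 16.4 ± 1.39 to 606 ± 4.94 FPKM (36.8-fold higher, log2 fold change 5.20, SE 0.06). In glycolysis 21 of 37 genes rose and 13 fell (camera adjusted p = 0.269), with a 77.6-fold rise of eno1 and a fall of hk1 (log2 fold change -4.51, SE 0.07). In gluconeogenesis 9 of 26 rose and 13 fell (adjusted p = 0.436), in glycogen metabolism 10 of 20 rose and 8 fell (adjusted p = 0.66) and in pentose phosphate and NADPH supply 2 of 11 rose and 6 fell (adjusted p = 0.111). Without a filter the pentose phosphate list passed as lower (adjusted p = 0.0226, range over the camera alternatives 0.0226 to 0.267). Lower examples were got1 (log2 fold change -3.10), a copy of the glucocorticoid receptor nr3c1 (-3.87), glycogen synthase gys2 (-1.59), gsk3b (-2.12) and transketolase, tkt (-2.99). The glycogen genes ugp2 and phka1a were higher. They had 7.79 to 8.54 and 7.15 to 8.26 FPKM in the knockdown libraries, against 1.91 to 2.79 and 2.46 to 3.51 in the controls. Medians and tests differed in sign for the lists of fatty acid uptake, lipoproteins, polyunsaturated fatty acids, glycogen, acute phase and circadian clock, none of which passed the threshold. Of the file's carbohydrate annotations, tested after the data had been seen, pyruvate metabolism (18 of 52 higher, 24 lower, median -0.14, adjusted p = 0.0304, adjusted p = 0.245 with an estimated correlation) passed as lower. So did starch and sucrose metabolism (15 of 33 higher, 15 lower, median -0.24, adjusted p = 0.0325, adjusted p = 0.244 with an estimated correlation). Ascorbate and aldarate metabolism (5 of 31 higher, 21 lower, camera adjusted p = 5.47e-08, adjusted p = 0.231 with an estimated correlation) passed as lower too. The same held for carbohydrate digestion and absorption (9 of 32 higher, 17 lower, adjusted p = 0.0304, adjusted p = 0.454 with an estimated correlation). Glycolysis and gluconeogenesis did not (26 of 68 higher, 29 lower, adjusted p = 0.365). Exocrine pancreas genes were left in these annotations too, and whether they made the lower calls was not tested.

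Of the 14 fixed lipid and glucose lists, insulin signalling alone passed the threshold, where 22 of 34 genes rose and 7 fell (median log2 fold change 0.81, camera adjusted p = 0.00119, adjusted p = 0.0726 with an estimated correlation). The file's wider annotation of insulin signalling, tested after the data had been seen, did not pass (62 of 131 genes higher, 43 lower, median 0.12, adjusted p = 0.34). The largest rises of the fixed list were in genes that insulin represses or that restrain insulin and growth signals. The insulin-like growth factor-binding protein 1 gene LOC100702148 rose from 3.4 ± 0.444 to 162 ± 6.03 FPKM (47.5-fold higher, log2 fold change 5.57, SE 0.08) and a second copy, igfbp1a, by a log2 fold change of 5.01 (SE 0.19). The mTOR inhibitor gene ddit4 (4.87, SE 0.17) and an insulin receptor substrate 2 gene (LOC100704325, 4.51, SE 0.13) were higher too. In the growth hormone and IGF axis 8 of 13 genes fell and 3 rose (median log2 fold change -0.70, adjusted p = 0.0324, adjusted p = 0.202 with an estimated correlation). That call was also lost with a minimum mean FPKM of 5 (adjusted p = 0.0699) and in every limma fit, and its adjusted p ranged from 0.00759 to 0.202 over the camera alternatives. The file's wider annotation of growth hormone synthesis, secretion and action, tested after the data had been seen, had its median on the other side of 0 and did not pass (46 of 93 genes higher, 32 lower, median 0.23, adjusted p = 0.664). Igf2 fell 6.31-fold (log2 fold change -2.66, SE 0.07) and igfals, which stabilises circulating IGF, fell (-1.70, SE 0.04), while cish, a feedback inhibitor of growth hormone signalling, rose (3.06, SE 0.10).

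Ribosomal and respiratory chain genes rose together, while amino acid breakdown fell. Of 83 genes of the cytosolic ribosome list 78 rose and 4 fell (median log2 fold change 0.76, camera adjusted p = 1.55e-16, adjusted p = 0.0934 with an estimated correlation). Their share of all reads was 9.51% ± 0.0536 in the knockdown and 5.54% ± 0.0573 in the control libraries (SD, n = 3). The ribosomal protein genes rplp2b, rpl38 and rps20 rose by log2 fold changes of 1.73, 1.66 and 1.53. A weakly read copy of elongation factor 2, eef2, fell (-2.11, SE 0.21). In oxidative phosphorylation 47 of 62 genes rose and 5 fell (median 0.72, adjusted p = 0.000342, adjusted p = 0.0934 with an estimated correlation), led by atp5mf, cox8a and cox7b (log2 fold changes 2.35, 1.95 and 1.83). The file's wider annotation of oxidative phosphorylation, tested after the data had been seen, did not pass (69 of 120 genes higher, 29 lower, median 0.41, adjusted p = 0.0805, adjusted p = 0.389 with an estimated correlation). Of 44 genes of amino acid breakdown and the urea cycle 27 fell and 10 rose (median -0.66, adjusted p = 1.64e-08, adjusted p = 0.046 with an estimated correlation). Betaine-homocysteine methyltransferase, bhmt, fell from 705 ± 17.2 to 10.9 ± 1.41 FPKM (log2 fold change -6.02, SE 0.06), prodha, which breaks down proline, fell by 5.06 on the log2 scale and agxtb by 3.73, while the urea cycle gene otc rose (log2 fold change 5.10, SE 0.16).

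Genes that fold and degrade proteins were lower as groups. In the endoplasmic reticulum stress list 29 of 36 genes fell and 5 rose (median log2 fold change -0.72, camera adjusted p = 0.00116, adjusted p = 0.0726 with an estimated correlation). The genes that fell included the chaperone BiP, LOC100708428, from 447 ± 8.12 to 92.6 ± 3.84 FPKM (log2 fold change -2.28, SE 0.04), and its cofactor dnajb11 (-2.08, SE 0.08), while the stress-induced regulators chac1 (2.58, SE 0.05) and ddit3 (2.45, SE 0.06) rose. Of 21 cytosolic heat shock genes 13 fell and 4 rose (median -1.02, adjusted p = 0.00298, adjusted p = 0.0934 with an estimated correlation), with log2 fold changes of -4.95, -4.07 and -3.67 for the chaperone genes hsp90aa1.2, dnajb1a and hspa4a. Of 35 proteasome genes 27 fell and 6 rose (median -0.73, adjusted p = 0.0145, adjusted p = 0.0934 with an estimated correlation), among them psmd11b (-2.49) and psme3 (-2.18). With a minimum mean FPKM of 5 the proteasome call was lost (adjusted p = 0.117, range over the camera alternatives 0.000178 to 0.117). The file's proteasome annotation, tested after the data had been seen, did not pass (11 of 48 genes higher, 32 lower, median -0.55, adjusted p = 0.149). Its annotation of protein processing in the endoplasmic reticulum did (34 of 164 higher, 107 lower, median -0.57, adjusted p = 0.000456, adjusted p = 0.231 with an estimated correlation).

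Immediate early, apoptosis and p53 target, inflammatory and complement genes were higher in the knockdown livers. Among immediate early genes, which respond within minutes to stimuli and handling, 16 of 23 rose and 3 fell (median log2 fold change 1.68, camera adjusted p = 0.000252, adjusted p = 0.122 with an estimated correlation). Cyr61, atf3 and per1b rose by log2 fold changes of 6.68, 5.77 and 4.87. In the list of apoptosis and p53 targets 15 of 22 genes rose and 4 fell (median 0.92, adjusted p = 0.00431, adjusted p = 0.0934 with an estimated correlation), a call lost with a minimum mean FPKM of 5 (adjusted p = 0.0699, range over the camera alternatives 0.000343 to 0.0934). Growth arrest genes gadd45b and gadd45g rose (5.81, SE 0.09, and 4.71, SE 0.13) and zmat3 had 1671 reads against 1 (ratio 1879, 95% interval 337 to 74243). Of 32 genes of inflammatory signalling 25 rose and 6 fell (median 1.79, adjusted p = 0.00028, adjusted p = 0.0648 with an estimated correlation), among them a toll-like receptor 5 gene (LOC100702807, log2 fold change 7.01, SE 0.20) and the prostaglandin synthase gene ptgs2 (4.77, SE 0.13). In the complement list 23 of 31 genes rose and 7 fell (median 0.66, adjusted p = 0.00028, adjusted p = 0.123 with an estimated correlation), with higher c1qb (2.72, SE 0.08) and cfd (1.95, SE 0.07). Several of the file's annotations on these themes, tested after the data had been seen, did not pass. They were apoptosis (63 of 121 higher, 39 lower, adjusted p = 0.191), p53 signalling (32 of 62 higher, 21 lower, 0.46) and complement and coagulation cascades (40 of 69 higher, 20 lower, 0.105). Nor did NF-kappa B signalling pass (51 of 84 higher, 22 lower, adjusted p = 0.0805), whereas TNF signalling was higher (64 of 98 higher, 21 lower, median 0.83, adjusted p = 0.00723, adjusted p = 0.231 with an estimated correlation). Toll-like receptor signalling (57 of 80 higher, 15 lower, camera adjusted p = 0.024) and cytokine-cytokine receptor interaction (70 of 106 higher, 24 lower, 0.0119) were higher too. With an estimated correlation each had an adjusted p of 0.231. No threshold was passed by the lists acute phase and coagulation (27 of 62 higher, 29 lower, adjusted p = 0.66), interferon and antiviral response (13 of 25 higher, 3 lower, 0.32) and hypoxia response (13 of 21 higher, 5 lower, 0.293). Nor was it by oxidative stress defence (adjusted p = 0.228, 15 of 51 higher, 29 lower), cell cycle (0.957, 9 of 17 higher, 5 lower) and circadian clock (0.99, 12 of 27 higher, 13 lower). Clock genes moved far in both directions (quartiles of the log2 fold change -2.40 and 1.58), which a test of a common direction cannot detect. The metabolic lists citric acid cycle (adjusted p = 0.22, 3 of 17 higher, 11 lower), bile acid synthesis and transport (0.22, 3 of 10 higher, 6 lower) and xenobiotic metabolism (0.22, 12 of 28 higher, 14 lower) did not pass either. Without a filter the citric acid cycle list passed as lower (adjusted p = 0.0436, range over the camera alternatives 0.0436 to 0.402). Of annotations tested after the data had been seen, the citrate cycle was lower (5 of 34 higher, 21 lower, median -0.61, adjusted p = 0.00935, adjusted p = 0.231 with an estimated correlation). Bile secretion (adjusted p = 0.0257, adjusted p = 0.231 with an estimated correlation) and drug metabolism by cytochrome P450 (adjusted p = 0.00238, adjusted p = 0.231 with an estimated correlation) passed as lower too. Primary bile acid biosynthesis (9 of 18 higher, 6 lower, adjusted p = 0.744) and metabolism of xenobiotics by cytochrome P450 (13 of 48 higher, 26 lower, 0.0549) did not.

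Transcripts of the exocrine pancreas, which in tilapia is scattered through the liver, were nearly missing from the knockdown libraries. They made up 0.039% ± 0.00905 of all reads in the knockdown and 4.88% ± 0.0302 in the control libraries (SD, n = 3). Of 31 tested genes 30 fell and 1 rose (median log2 fold change -6.94, or -6.88 with genes at 0 reads set at their bound, camera adjusted p = 8.12e-76, adjusted p = 0.046 with an estimated correlation). Chymotrypsinogen A, LOC100691584, fell from 310 ± 8.53 to 0.834 ± 0.28 FPKM, a bile salt-activated lipase, LOC109199076, from 1077 ± 85.3 to 4.6 ± 2.06 FPKM. The phospholipase gene pla2g1b had 167 reads in the controls and 0 in the knockdown (at least 49.5-fold lower). The member that rose, a carboxypeptidase A1 copy (LOC100708903, named after its value was seen), had a log2 fold change of 2.59. Erythrocyte genes were lower as well, at 0.189% ± 0.00731 of reads against 1.14% ± 0.0188, with 17 of 18 genes lower and 1 higher (median -2.06, adjusted p = 1.03e-10, adjusted p = 0.0622 with an estimated correlation). A hemoglobin beta gene, LOC100704059, fell from 6890 ± 9.8 to 570 ± 8.74 FPKM and an alpha gene, LOC102080222, from 8074 ± 159 to 1067 ± 28.6 FPKM.

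Markers of immune, vascular and bile duct cells were higher in the same libraries, although the lists hold genes that liver cells also use. Apoc1, in the macrophage list, had 26447 ± 366 and 21822 ± 539.9 FPKM in knockdown and control livers, and a leukocyte cell-derived chemotaxin-2 gene in the granulocyte list, LOC100706937, had 29049 ± 1204 and 4848 ± 206 FPKM (both named after their values were seen). All 19 macrophage genes rose (median log2 fold change 1.84, camera adjusted p = 3.19e-06, adjusted p = 0.0622 with an estimated correlation), among them a macrophage colony-stimulating factor 1 receptor gene (LOC100710555, 4.17, SE 0.13), spi1a (3.47, SE 0.29) and marco (2.85, SE 0.28). Of 11 granulocyte genes 9 rose and 1 fell (median 2.57, adjusted p = 0.00503, adjusted p = 0.0934 with an estimated correlation), including csf3r (3.52, SE 0.17) and mmp9 (2.93, SE 0.12), but with a minimum mean FPKM of 5 that call was lost (adjusted p = 0.136, range over the camera alternatives 0.00193 to 0.136). Of 6 genes of T and natural killer cells 5 rose and 0 fell (median 1.27, adjusted p = 0.0408, adjusted p = 0.305 with an estimated correlation). That call was lost without knockdown library 1 (adjusted p = 0.0564), without control library 3 (0.0513) and without a filter on low values (0.466, with a median of -0.54), its adjusted p ranging from 0.0107 to 0.466 over the camera alternatives. Endothelial genes rose in 19 of 21 cases and fell in 1 (median 1.28, adjusted p = 0.00772, adjusted p = 0.0934 with an estimated correlation), with lyve1 and stab2 at log2 fold changes of 3.17 and 2.98. Of 10 bile duct genes 9 rose and 0 fell (median 1.79, adjusted p = 4.3e-05, adjusted p = 0.0648 with an estimated correlation), led by epcam and cdh1 (3.35 and 2.70). Of 9 adipocyte genes 7 rose and 2 fell (median 1.77, adjusted p = 0.00431, adjusted p = 0.0934 with an estimated correlation), of which 7 also belong to other lists, pnpla2 and lipea among them, and leptin, lepa, had a log2 fold change of 2.87. Stellate cell and fibroblast genes (12 of 22 higher, 4 lower, adjusted p = 0.307) and hepatocyte identity genes (8 of 23 higher, 11 lower, adjusted p = 0.1, 17 of them also in other lists) did not pass. The hepatocyte list passed as lower without a filter (adjusted p = 0.004), without control library 1 (0.0286) and with DESeq2 (0.0421), its adjusted p ranging from 0.004 to 0.432 over the camera alternatives. Its share of reads was 8.31% ± 0.011 in the knockdown and 10.9% ± 0.182 in the control libraries. Transcripts known to stay in the nucleus or unspliced were higher, 12 of 17 rising and 3 falling (median 0.80, adjusted p = 0.000114, adjusted p = 0.0648 with an estimated correlation), such as rbm5 (2.77, SE 0.04) and nktr (2.20, SE 0.05). These shifts in cell type markers and RNA signs went with the same 3 libraries as each change of lipid, glucose, ribosomal and stress genes given above.

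**Figure D3:**
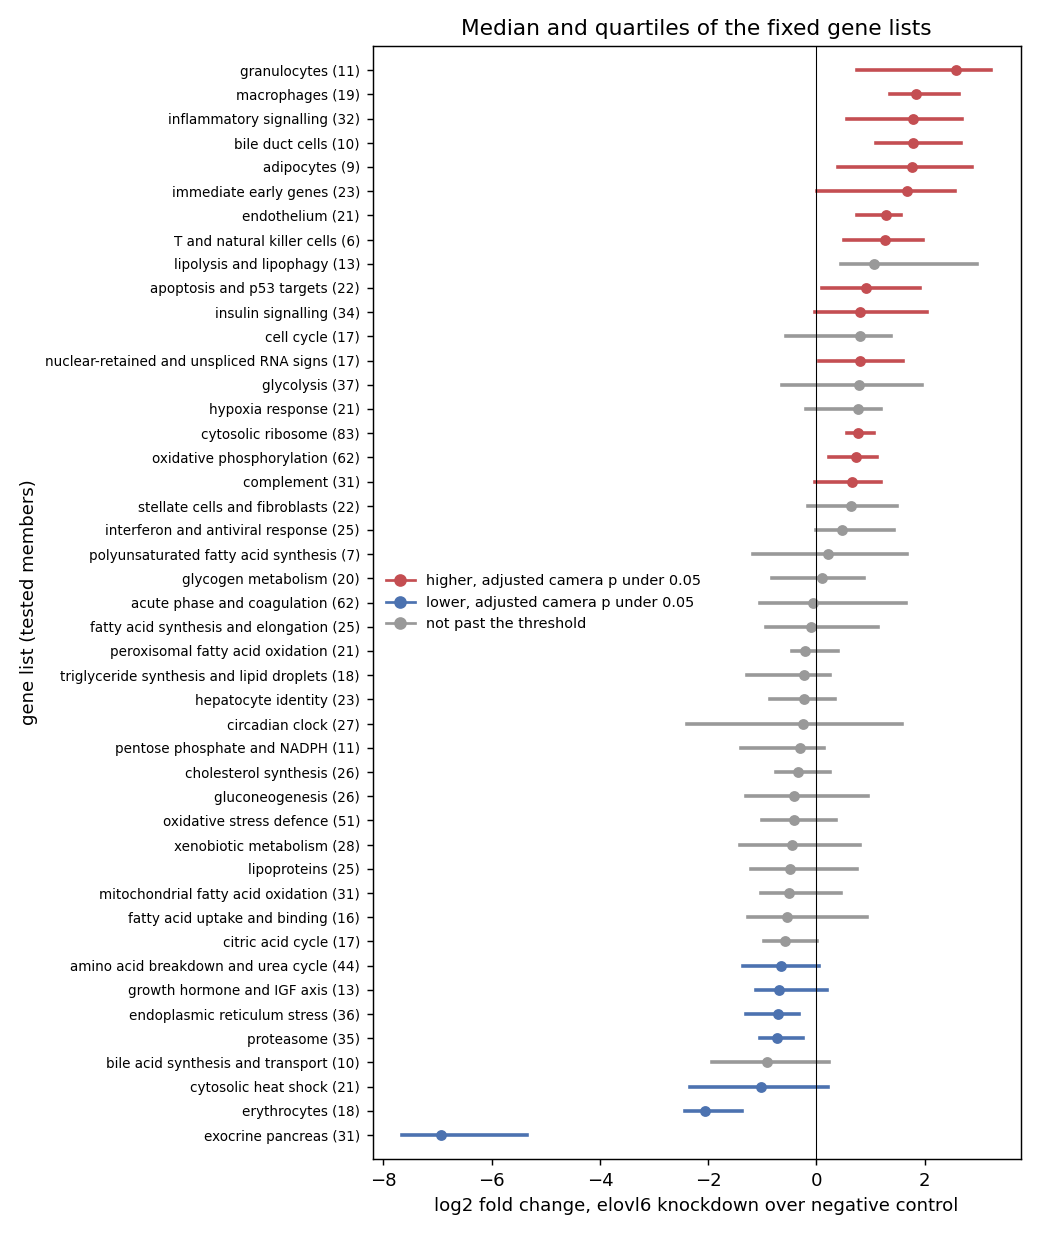
Median (point) and quartiles (line) of the log2 fold change, knockdown over control, of the tested members of each of the 45 gene lists, with the number of members in parentheses. Red and blue lists were higher and lower than other genes at an adjusted camera p under 0.05 with a preset correlation, and grey lists did not pass. Exocrine pancreas genes lie lowest, at a median of -6.94, and granulocyte genes highest, at 2.57.

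In all, 21 of the 45 lists passed the camera threshold with the preset correlation, 14 higher and 7 lower, and 2 of them, exocrine pancreas and amino acid breakdown, with an estimated correlation, while fry called 42. The lost calls did not all come from a higher correlation, as the test then also rests on few residual degrees of freedom. The estimate lay below the preset 0.01 for macrophages (-0.044), whose unadjusted camera p still rose from 3.54e-07 to 0.00521, and for bile duct cells (-0.101). For other lists, such as the cytosolic ribosome (0.139), it lay above. Of the 21 lists, 16 passed in every alternative other than the estimated correlation.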

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

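The tests added after the data had been seen were DESeq2, limma on log2(FPKM + 1), scaling by library size alone and leaving out the exocrine pancreas list before scaling. The log2 fold change of elovl6 stayed between -2.28 and -1.97 and past the threshold in 22 alternatives, and between -2.15 and -2.10 when each library was left out. Of 153 other named genes, 3314 of 3315 values kept their direction and call, the exception being a lectin gene, LOC106097545, under limma with robust moderation (adjusted p = 0.0944, log2 fold change -2.25). The naming rule mostly took genes with the largest changes in this same fit, so this says little about the other called genes. The count of changed genes fell from 8938 to 4662 (2341 higher, 2321 lower) with a minimum mean FPKM of 5, where 5469 genes were tested, to 4907 (2523 and 2384) with a minimum change of 2-fold, and to 4909 (2525 and 2384) at an unadjusted p under 0.05 with that minimum. It was 8531 to 8784 with a library left out, 8782 with DESeq2, 8890 with limma and 11873 without a filter. Leaving out a library gave 20 to 22 lists, and 7997 genes were called in the full fit and in each of these 6. The replicate block gave 8856 genes (4409 higher, 4447 lower), 21 lists and a log2 fold change of -2.12 for elovl6. Deviations of same-numbered libraries had correlations of 0.00106, 0.0067 and 0.00174, so no effect shared by equal numbers was seen. Libraries of unlike number had -0.00868 to 0.00708. These values cannot show whether equal numbers belong together. Against limma on log2(FPKM + 1), TPM moved the median log2 fold change of all genes from -0.00219 to -0.13, and scaling without the 20 highest genes to -0.17, so changes under these are relative to that shift (44.5% and 42.2% of calls higher, against 4455 of 8890).

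Lists past the threshold numbered 21, 2 with an estimated correlation and 42 by fry. Lipid and glucose lists numbered 1, 4 without a filter (mitochondrial and peroxisomal fatty acid oxidation and pentose phosphate joined insulin signalling), 2 in each of 9 limma fits and without the exocrine pancreas list, 0 with an estimated correlation and 13 by fry. Of 1077 list values 997 kept direction and call, 34 lost and 38 gained the call with the direction kept, and 8 changed the sign of the median. Without a filter these were T and natural killer cells (-0.54, which also lost its call), circadian clock (0.20) and glycogen metabolism (-0.33). At a minimum mean FPKM of 5 they were circadian clock (0.45) and lipoproteins (0.11). Glycogen metabolism had -0.031 on TPM and -0.061 without the 20 highest genes. The median of all genes had moved to -0.13 and -0.17 under these scalings, so the glycogen list stayed above it. Hepatocyte identity had -0.37 to 0.00413 with a library left out. For the other sign changes the cause was not tested, beyond that other filters change which genes are tested. The rule for a changed direction was set after a first version, by the direction of the test, had been seen. That version counted 63 values, 0 of them in lists that passed the threshold. At this depth a group at 0 reads gives only a bound, as for pla2g1b (at least 49.5-fold lower).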

Other observations

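Of the tests below, those of pathway annotations, of pancreatic tissue, of inherited copies and of reads assigned to near-identical copies were chosen after the results they concern had been seen, and the summed reads of copies were tested after other tests of that pattern. The test of scaling for ribosomal genes was narrowed to quantile normalization, and its interval added, after its values were seen, and that of scaling for the exocrine pancreas was replaced after a first version had been seen. Genes of ribosome assembly fell although ribosomal protein genes rose. Of 67 genes annotated to ribosome biogenesis 55 fell and 4 rose (median log2 fold change -1.39, camera adjusted p = 1.91e-06, adjusted p = 0.183 with an estimated correlation), among them nop58, a core protein of the particles that modify ribosomal RNA, from 54.3 ± 0.751 to 8.44 ± 0.993 FPKM (SD, n = 3), and the methyltransferase gene fbl (-1.71, SE 0.07). Of 16 genes of the folate one-carbon pool 13 fell and 1 rose (median -1.52, adjusted p = 1.03e-05, adjusted p = 0.231 with an estimated correlation), with mthfd1 at a log2 fold change of -3.24 (SE 0.08) and the purine synthesis gene gart at -2.67 (SE 0.14). Of 105 genes of transport between nucleus and cytoplasm 72 fell and 16 rose (median -1.08, adjusted p = 0.00114, adjusted p = 0.231 with an estimated correlation), including the importin gene ipo5 (-2.71, SE 0.07) and the pore gene nup155 (-3.35, SE 0.17). In N-glycan synthesis 35 of 44 genes fell and 5 rose (median -1.02, adjusted p = 0.00114, adjusted p = 0.231 with an estimated correlation), such as rpn2 (-2.48, SE 0.08). Of 337 pathways 40 passed with the preset correlation and 0 with an estimated one by camera. Examples were named after their values were seen.

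Exocrine pancreas genes were lower in all 3 knockdown libraries, trypsin prss1 falling from 19894 ± 197 to 94.5 ± 35 FPKM and ela2 from 5919 ± 51.1 to 43.5 ± 7.84 FPKM (both named after their values were seen). A shift of scaling by these abundant genes is argued against, since taking them out of the library totals moved the median log2 fold change of the other genes by -0.07 and the counts of higher and lower genes by a ratio of at most 1.06. Less pancreatic tissue in the knockdown samples cannot be told apart from lower expression of the acinar program in the same amount of tissue, through elovl6 or otherwise. The 4 acinar genes of the list that are not digestive enzymes had a median log2 fold change of -3.59, but they belong to the pattern itself, so their fall decides nothing. Of these, erp27 had -7.37, but pdia2 (-4.01), rbpjl (-3.16) and bhlha15 (-2.48) fell less than the list's median of -6.94, so loss of tissue alone would need reads of these 3 from other cells, which was not tested.

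Genes with at least 50 reads in each library of 1 group and at most 3 reads in the other group together numbered 93, 61 read in the knockdown and 32 in the control libraries, 50 of them at 0 reads in the other group. Reads moved between same-named copies within 1 Mb are argued against as the whole cause for the 29 genes that have such copies. The summed reads of the copies had a median absolute log2 ratio of 5.72 and 22 of 29 were at least 8-fold apart. This count is over genes, so the sums of 3 pairs of genes that share copies (12.34, 8.66 and 7.85) enter more than once. In contrast, the 42 copies of the MHC class I-related gene LOC100692201 summed to a log2 ratio of 0.074. Sharing of a product name within 1 Mb was found for 39.7% of the genes with a named product, against 8.23% of all tested genes with one, but only 78.5% have one and the share over all 93 could be 31.2 to 52.7%, so this check of near-identical copies is void and they cannot be told apart from other causes for the rest. Inherited differences in gene copies between the sets of fish could give such genes and also stay open. Opposite-direction pairs of same-named genes numbered 0, at or below the shuffles' median of 1 that had been set against this explanation, but with 3 pairs in all 0 lies within the spread of the shuffles, so that bound was replaced after the value was seen by the shuffles' 2.5% quantile, which is 0, so that no count could lie below it.

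Ribosomal protein and respiratory chain genes, 145 in all, had a median log2 fold change of 0.75 and a median length of 684 bp, against 2762 bp for other tested genes. Scaling between libraries is argued against as the whole cause, though it may explain part, since under quantile normalization the excess over all genes was 0.50 (95% interval 0.36 to 0.67 over resampled members, taken as independent), against 0.76 with TMM. A bias by gene length may explain part of the rise, since lists matched on length had a median of medians of 0.43 and a highest of 0.91. Over 5 groups of the other tested genes of rising length, the median log2 fold change was 0.083, -0.17, -0.14, 0.034 and 0.053, with no steady trend. The shortest group spans 346 to 1642 bp, too wide to show a bias among genes near 684 bp. These 5 values therefore do not decide on length. At the same time, only 5 of 1000 matched lists reached the value observed, with their genes drawn as independent. A response to the knockdown beyond length was not tested separately and stays open.

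There are 10 splits of the 6 libraries into 3 and 3, too few for a share under 0.05. The real split gave 8938 changed genes and the highest other split 0, so 1 split gave as many. It gave 21 gene lists, the highest other 16, again 1 split. For lipid and glucose lists it gave 1 and the highest other 2, and 8 of the 10 splits gave as many. Each other split joins 2 libraries of 1 group with 1 of the other, so the difference between the groups adds to the spread within its sets. Part of that difference also stays between the sets, and each of these splits called 12 to 16 lists. These splits therefore cannot show how many genes or lists chance alone would give.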
